A study of Homo sapiens with 6 samples.

How the data were processed

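Messenger RNA of A549 cells was profiled in 6 libraries, 3 labelled siNC and 3 labelled siFOXD3, and each library came with 1 table of gene symbols and values. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit, and per the series' design text sequencing was on an Illumina Genome Analyzer. Per the labels' protocols the extracted material was retina, while the tissue and cell type labels name the lung cancer line A549; the cell type label was followed, and photoreceptor markers were examined. Per the submitters' processing notes, TopHat, Cufflinks and the genome build hg19 were used; their versions, the annotation, the read length and the handling of strand are not given in the sources used here. The siRNA sequences, the dose and the time between transfection and harvest are likewise not given in the sources used here.

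The values the authors deposited are FPKM per gene symbol, the unit named per the file headers, a value scaled by transcript length and by library size. Sums of FPKM ran from 596623 to 618389 per library. Of 17787 symbols listed in any file, 14465 were in all files, and of the 3322 absent from at least 1 file, 94.1% stayed under 1 FPKM everywhere. An absent symbol was set to 0. Symbols on several rows of a file (333) were summed. Of the symbols, 26 had been turned into dates, as spreadsheet programs do, and 18 of these were tested; none is named. Since reads were counted without a stated use of strand, and reads shared between near-identical genes can be split or lost, values of multigene families, of genes with many pseudogenes and of overlapping genes are uncertain.

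FPKM values are not counts, so tests were run on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), with the group as the only term and Benjamini-Hochberg adjustment over the genes tested. A gene was tested with at least 1 FPKM in at least 3 of the 6 libraries (12555 genes), and called at an adjusted p under 0.05, two-sided. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for the other steps and matplotlib 3.10.9 for the figures. Means are given with the SD over 3 libraries. Exact permutation tests of 3 libraries against 3 cannot give a p under 0.1.

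The genes named were fixed by rule: FOXD3, WDR5 and SET; the 10 largest rises and 10 largest falls in log2 fold change among called genes whose groups did not overlap, leaving out symbols of noncoding or unnamed loci; the 5 called higher and 5 called lower with the highest mean FPKM; and up to 4 called members of each list with the largest change, or the 2 most abundant members where fewer than 2 were called. Some genes that the rule selects are not reported here. In the text on leukocyte, airway, hepatocyte and neural markers, PTPRC, MUC5B, HNF4A and TUBB3 were added after their values were seen. The 46 gene lists, covering pathways, complexes, quality and cell types, were tested with camera (preset correlation 0.01) where at least 5 members passed the filter, with Benjamini-Hochberg adjustment over the 38 lists tested, and also with camera at an estimated correlation and with fry.

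Depth is not given in the files. It was estimated from the steps between low values of genes with a single annotated transcript of 700 to 4000 bases, with an assumed fragment length of 150 bases, at 7650000, 8510000 and 8330000 fragments for siNC and 8640000, 7790000 and 8950000 for siFOXD3. On 6 simulated libraries of known depth, with transcript lengths scattered by 10% (SD), the step recovered fragments within 10.4%. Squared differences between libraries of 1 group were divided by the variance that counting noise gives at the estimated depth. Their median over genes was 1.22 to 2.07 times that of counting noise alone. Their mean was 1.71 to 3.98, where counting noise gives 1. Each library was kept as its own sample. Counting intervals from this estimate cover counting error only, since reads without molecular identifiers are not independent molecules. GENCODE 29 supplied transcript lengths, sequences and the order of genes; it is on another build than hg19, so no coordinates are given, and 12126 of the tested genes (96.6%) had a match.

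The fit was tested on simulated data for the same 12555 genes and the same 3 against 3 libraries, with 200 genes changed and the 20 tested Notch pathway genes changed by 0.5 to test the list step. It recovered 11.9% of genes changed by 0.25 on the log2 scale, 61.2% of those changed by 0.5 and 92.4% of those changed by 1, with 3 false calls (2.4% of all calls, those of the Notch genes included). Far fewer genes were changed there than the 8278 called in the data, which makes the Benjamini-Hochberg adjustment stricter. These recoveries therefore do not give the share of changes missed in the real comparison. Alternatives were a pseudocount of 0.1 or 5, no filter, a stricter filter (mean of at least 5 FPKM), rescaling to TPM, median-of-ratios scaling, quantile normalization, limma without trend and robust, array weights, the replicate number as a block, repeated symbols left out, absent genes treated as missing, each library left out in turn, an adjusted p of 0.01, and a test against a fold of 1.2.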

Results

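RNA was sequenced from A549, a human cell line derived from a lung adenocarcinoma, in 6 libraries. The labels put 3 libraries in a group named siNC, with the genotype label wild type, and 3 in a group named siFOXD3, named for a small interfering RNA (an RNA used to lower the messenger RNA of one gene) against FOXD3. The labels do not spell out siNC, which served as the control group. The files give 1 FPKM value (sequenced fragments scaled by transcript length and library size) per gene symbol and library. The siNC libraries listed 16227, 16245 and 16286 symbols and the siFOXD3 libraries 15752, 15649 and 15692. At 1 FPKM or more there were 12540, 12615 and 12680 symbols in the siNC libraries and 12007, 11947 and 12007 in the siFOXD3 libraries. The files hold no read counts, and the steps between low values gave an estimate of 7650000 to 8950000 fragments per library, with relative depths between 0.992 and 1.078 times that of siNC replicate 1. Over the 12555 genes tested, libraries of 1 group correlated across genes at r = 0.985 to 0.991 and libraries of different groups at r = 0.937 to 0.948, where genes are not independent replicates. The labels do not state that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

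The series title names WDR5 and SET as genes that FOXD3 represses, and the comparison of siFOXD3 with siNC asks which genes differ when FOXD3 is lowered. FOXD3, a forkhead transcription factor known from the neural crest and from pluripotent cells, was close to the detection limit in every library. It was listed at 0.152, 0.291 and 0.134 FPKM in siNC replicates 1 to 3 and at 0.0749 FPKM in siFOXD3 replicate 2, and it was not listed in siFOXD3 replicates 1 and 3. WDR5, a shared subunit of the SETD1/MLL histone methyltransferase complexes, rose from 20.1 ± 1.14 FPKM in siNC to 34.0 ± 1.63 FPKM in siFOXD3 (mean ± SD, n = 3 each), a ratio of 1.69. SET, a histone chaperone and phosphatase inhibitor, rose from 217 ± 8.26 to 318 ± 7.60 FPKM, a ratio of 1.46.

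The FOXD3 values correspond to an estimated 2, 5 and 2 fragments in the siNC libraries and 1 in the siFOXD3 libraries together, with 3 fragments, the limit that a count of 0 allows, worth 0.177 FPKM in siFOXD3 replicates 1 and 3. The ratio of estimated fragments was 0.105 (95% exact interval 0.0024 to 0.761, two-sided exact binomial p = 0.0099), which covers counting error only and rests on an assumed fragment length. The siFOXD3 mean was 13.0% of the siNC mean, and it was 0% without siFOXD3 replicate 2, 17.5% without siNC replicate 2 and 19.5% without siFOXD3 replicate 1 or without siFOXD3 replicate 3. FOXD3 was below the filter on low values, and in a fit with no filter its log2 fold change was -0.22 ± 0.06 (SE, limma, Benjamini-Hochberg adjusted p = 0.0221). WDR5 rose by 0.73 ± 0.06 on the log2 scale (SE, limma, Benjamini-Hochberg adjusted p = 4.21e-06) and SET by 0.55 ± 0.05 (adjusted p = 2.98e-06). For each of FOXD3, WDR5 and SET the 3 values of 1 group lay on the same side of the 3 of the other, and the two-sided exact permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. Among called genes, 642 (5.1% of the genes tested) had a log2 fold change at least as high as WDR5 and 1206 (9.6%) at least as high as SET. Compared with the 500 genes nearest in mean level, WDR5 rose more than 94.4% and SET more than 82.6%. Reads of SET can be shared with its processed pseudogenes, so its level is uncertain to that extent.

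**Figure D1:**
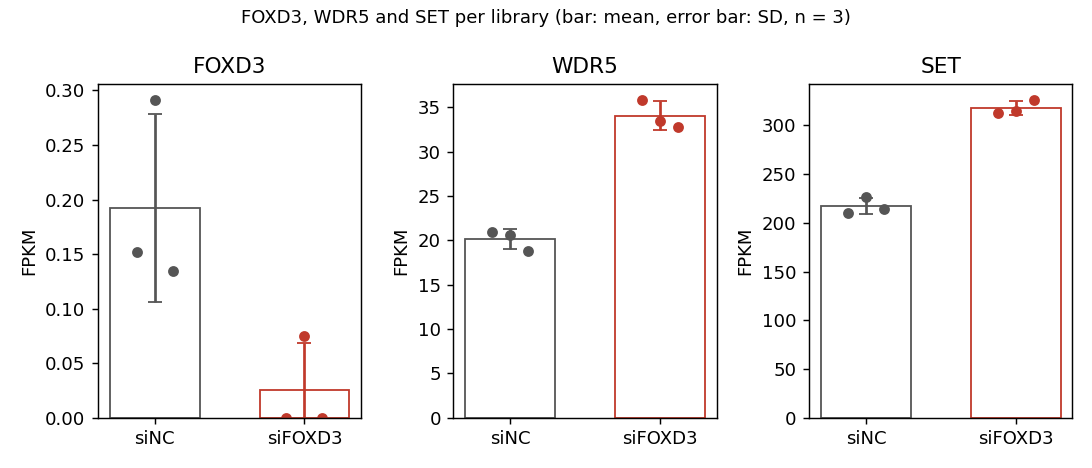
FPKM of FOXD3, WDR5 and SET in each library (points), with the group mean (bar) and SD (error bar, n = 3) and the group on the horizontal axis. FOXD3 lay between 0.134 and 0.291 FPKM in siNC and was listed in 1 siFOXD3 library, at 0.0749 FPKM, while the siFOXD3 values of WDR5 and SET lay above all siNC values.

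The 10 largest falls under the naming rule included acute phase, chemokine and S100 genes. SAA1, an acute phase apolipoprotein, fell from 747 ± 143 FPKM in siNC to 3.91 ± 0.712 FPKM in siFOXD3 (log2 fold change -7.24), and SAA2 from 178 ± 32.6 to 0.548 ± 0.156 FPKM (-6.84). IL8, a chemokine that attracts neutrophils, fell from 41.8 ± 3.16 to 1.24 ± 0.0785 FPKM (-4.26), and the related CXCL1 from 11.3 ± 2.47 to 0.218 ± 0.159 FPKM (-3.32). IL6, the cytokine that drives the acute phase response, fell from 19.8 ± 1.44 to 0.794 ± 0.424 FPKM (-3.56). The calprotectin subunit S100A8 fell from 724 ± 132 to 55.1 ± 2.81 FPKM (-3.67), and S100A7, an antimicrobial protein of skin, was listed at 19.5, 12.1 and 19.3 FPKM in siNC and in no siFOXD3 library. PDZK1IP1, a small membrane protein, fell from 149 ± 19.1 to 4.24 ± 1.03 FPKM (-4.85) and C15orf48 from 97.5 ± 3.87 to 6.30 ± 0.556 FPKM (-3.76). SAA2-SAA4, a readthrough transcript, averaged 12.6 ± 1.39 FPKM in siNC and was at 0.519 FPKM or less in siFOXD3. SAA1, SAA2 and SAA2-SAA4 overlap or are near copies of each other, so the split of reads among them is uncertain. The log2 fold changes of lower genes moved with the pseudocount: with pseudocounts of 0.1 and 5, S100A7 was at -7.38 and -2.12, SAA2-SAA4 at -6.10 and -1.76 and CXCL1 at -5.25 and -1.63, and with a pseudocount of 5 IL6 was at -2.10.

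Among the rises, TFF1, a secreted trefoil peptide of mucosal epithelium, went from 2.10 ± 0.372 to 44.3 ± 5.38 FPKM, a ratio of 21.0 and a log2 fold change of 3.87. KRT4, a keratin of stratified mucosa, rose from 1.78 ± 0.254 to 12.3 ± 0.895 FPKM (2.26, and 1.35 with a pseudocount of 5). SPP1, which encodes the matrix protein osteopontin, rose from 36.1 ± 6.56 to 171 ± 4.50 FPKM (2.22). DIO2, which activates thyroid hormone, rose from 20.3 ± 2.61 to 83.8 ± 2.27 FPKM, a ratio of 4.14, and GAL, the neuropeptide galanin, from 13.6 ± 1.52 to 55.8 ± 3.32 FPKM (1.96). GPX2, a glutathione peroxidase, rose from 112 ± 7.99 to 418 ± 6.56 FPKM (1.89). SPANXA2, of a sperm protein family, rose from 23.9 ± 5.77 to 155 ± 1.99 FPKM (2.68) and its relative SPANXB2 from 29.8 ± 11.3 to 98.0 ± 2.50 FPKM (1.74). ATAD3B, a mitochondrial ATPase, rose by 1.92 and ALPP, placental alkaline phosphatase, by 1.74. SPANXA2, SPANXB2, ATAD3B and ALPP have near-identical copies that can share reads, so their levels are uncertain. Over these rises and the falls above, the largest limma, Benjamini-Hochberg adjusted p was 0.00188, for SPANXB2, and the siNC and siFOXD3 values of each gene did not overlap.

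Among the most abundant genes that were called higher, the epithelial keratins KRT8 (2059 ± 253 to 3203 ± 12.9 FPKM, log2 fold change 0.64) and KRT18 (0.34) and the glycolytic enzyme GAPDH (7450 ± 193 to 9761 ± 49.2 FPKM, 0.39) rose, with CHCHD2, a mitochondrial protein (0.23), and FTL, the ferritin light chain (0.11). Among the most abundant called lower, the ferritin heavy chain FTH1 fell from 5910 ± 118 to 4664 ± 53.3 FPKM (-0.34), and the ribosomal protein genes RPS18 (-0.58), RPS12 (-0.35), RPL39 (-0.18) and RPL41 (-0.14) fell as well. Quantile normalization moved KRT18 to 0.56, CHCHD2 to 0.46, FTL to 0.40, RPS18 to -0.22 and RPL39 to -0.28, turned RPL41 to 0.25 and RPS12 to 0.04, and took FTH1 to -0.08 with a limma, Benjamini-Hochberg adjusted p of 0.073. With median-of-ratios scaling FTL was at 0.20, RPL39 (-0.09, adjusted p = 0.0619) and RPL41 (-0.05, adjusted p = 0.33) were no longer called, and with limma without trend and robust neither FTL (adjusted p = 0.125) nor RPL41 (0.0829) was called. FTL lost its call without siNC replicate 3 (adjusted p = 0.0556) and without siFOXD3 replicate 1, 2 or 3 (0.0872, 0.0583 and 0.0589), and RPL41 without siFOXD3 replicate 1 or 2 (0.0558 and 0.0592). Most of these abundant genes have processed pseudogenes, which can share their reads.

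**Figure D2:**
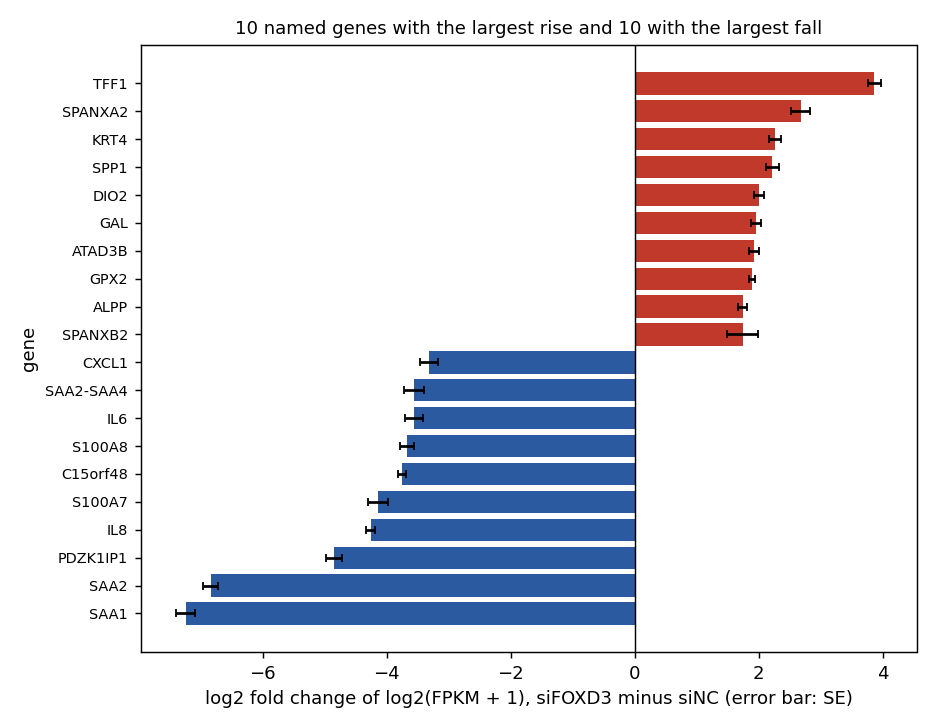
Log2 fold change of log2(FPKM + 1), siFOXD3 minus siNC, for the largest rises and falls under the naming rule fixed in advance, with the SE of the limma fit (error bar). SAA1 and SAA2 lie lowest, at -7.24 and -6.84, and TFF1 highest, at 3.87.

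Across all 12555 genes tested, limma with Benjamini-Hochberg adjustment called 8278 (65.9%), 3415 higher and 4863 lower in siFOXD3. By at least 1 on the log2 scale, 219 genes rose and 750 fell. The values of the groups did not overlap for 8873 genes (70.7%), where chance gives 10%, and 8113 genes were both called and without overlap. A limma test against a fold of 1.2 called 4297 genes, 1621 higher and 2676 lower. The balance of directions moved with the scaling of the values: 58.7% of the called genes were lower as deposited, 50.1% with median-of-ratios scaling (4140 higher, 4154 lower) and 47.4% with quantile normalization (4255 higher, 3835 lower). The median log2 fold change of all genes was -0.08 as deposited and 0.03 with quantile normalization. Relative to the all-gene median, the Polycomb, epithelial junction and pluripotency lists had medians of -0.03 each, the Notch list -0.01, the Wnt list 0.02 and the histone list 0.16.

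Of 46 gene lists fixed in advance, 38 had at least 5 tested members, and camera with a preset correlation of 0.01 called 11 higher, 11 lower and 16 neither way. With an estimated correlation, the calls that held were those of mitosis, splicing and NF-kB genes, with adjusted p = 0.0279 for each. The p-values of lists below are camera's, adjusted over the 38 lists, and the counts of genes are from limma with Benjamini-Hochberg adjustment over all genes tested. The count adjusted over the list alone was the same for every list except where it is given.

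Inflammatory genes were lower in siFOXD3. All 22 tested NF-kB and inflammatory cytokine genes fell (22 adjusted over the list alone), with a median log2 fold change of -1.88 (adjusted p = 5e-11). They include IL8, IL6 and CXCL1, and TNF, a central inflammatory cytokine, which fell from 7.81 ± 1.40 to 0.101 ± 0.112 FPKM. All 8 tested complement and acute phase genes fell, of 16 listed, with a median of -2.98, and -1.11 with no filter (adjusted p = 3.01e-06, and adjusted p = 0.187 with an estimated correlation). Among these, LCN2, an iron-binding defence protein, fell from 2645 ± 380 to 313 ± 18.1 FPKM (-3.06) and CFB, complement factor B, from 233 ± 25.2 to 24.7 ± 1.90 FPKM (-3.18). Of 34 interferon-stimulated genes, 31 fell (32 adjusted over the list alone) and none rose, with a median of -0.73 (adjusted p = 1.29e-07, and adjusted p = 0.187 with an estimated correlation). Among them were OASL, an antiviral protein (86.2 ± 6.58 to 33.7 ± 2.87 FPKM), STAT2, a transcription factor of the interferon response (-1.23), IFITM1 (-1.65) and GBP1 (-1.24). Of 16 immediate-early genes, 13 fell and 2 rose, with a median of -0.48 (adjusted p = 0.00971, and adjusted p = 0.187 with an estimated correlation), and the transcription factors EGR1 (-1.19) and ATF3 (-1.80) and the phosphatase DUSP1 (-1.42) were among those that fell.

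Some leukocyte markers moved with these lists. LCP1, an actin-bundling protein of leukocytes and many carcinoma lines, fell from 95.2 ± 6.89 to 25.5 ± 1.85 FPKM, LAPTM5 from 2.06 ± 0.241 to 0.210 ± 0.0691 FPKM and CD14 from 2.92 ± 0.613 to 1.25 ± 0.304 FPKM. PTPRC, the common leukocyte antigen, lay at 0.227 FPKM in siNC and 0.194 FPKM in siFOXD3. Of the 17 leukocyte markers, 4 were at 1 FPKM or more in any siNC library and 3 in any siFOXD3 library. TNF and CFB lie in the major histocompatibility region, whose alternative haplotypes can put a gene on several rows, which were summed.

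Genes of cell growth and division were higher in siFOXD3. Of 35 mitosis and G2/M genes, 34 rose and none fell, with a median log2 fold change of 0.86 (adjusted p = 8.63e-17). CDC20, an activator of the anaphase-promoting complex, rose from 54.5 ± 7.43 to 150 ± 8.45 FPKM (1.46), and the mitotic kinesins KIF20A (20.4 ± 0.428 to 58.5 ± 1.68 FPKM, 1.48) and CENPE (1.45) rose as well. Of 32 DNA replication and G1/S genes, 30 rose and 1 fell, with a median of 0.85 (adjusted p = 7.52e-13, and adjusted p = 0.187 with an estimated correlation). The list includes CDC6, which loads the replicative helicase (12.8 ± 0.341 to 29.7 ± 0.670 FPKM), the cyclin CCNE2 (1.43), GINS4 (1.43) and UHRF1 (1.16). Of 31 ribosome biogenesis and MYC target genes, 29 rose and 1 fell, with a median of 0.88 (adjusted p = 1.51e-13, and adjusted p = 0.0569 with an estimated correlation). Among them SRM, which makes the polyamine spermidine, rose from 25.6 ± 3.33 to 77.8 ± 4.13 FPKM (1.57) and NOP16, a nucleolar protein, from 21.2 ± 1.10 to 63.0 ± 1.02 FPKM (1.53).

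Of 34 splicing factor genes, 28 rose and none fell, with a median of 0.48 (adjusted p = 2.84e-11), and SRSF2, which binds exonic enhancers, rose from 87.0 ± 8.25 to 224 ± 9.34 FPKM (1.36). Of 30 DNA repair genes, 18 rose and 3 fell, with a median of 0.38 (adjusted p = 0.000924, and adjusted p = 0.116 with an estimated correlation). The mismatch repair gene MSH6 (0.60) and the recombination genes XRCC2 (0.80) and XRCC3 (0.59) were among those that rose. Of 12 replication-dependent histone genes, 3 rose and 3 fell (2 adjusted over the list alone), with a median of 0.08 (adjusted p = 0.623). HIST1H2BC rose from 3.39 ± 0.515 to 8.08 ± 2.45 FPKM and HIST3H2A fell from 20.5 ± 4.39 to 9.06 ± 2.60 FPKM. Most histone messages of this class lack poly(A) tails, and their near-identical copies can share reads.

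WDR5 and SET are themselves members of the lists named for their complexes and partners. Of 19 SETD1/MLL complex genes, 9 rose, 1 fell and 9 were not called, with a median of 0.16, or 0.24 above the all-gene median, and 0.27 with quantile normalization (adjusted p = 0.0185, and adjusted p = 0.187 with an estimated correlation). Besides WDR5, HCFC1, a scaffold for chromatin regulators, rose from 14.3 ± 1.38 to 24.1 ± 0.699 FPKM (0.72) and C16orf53, also known as PAGR1, from 4.23 ± 0.159 to 7.54 ± 0.185 FPKM (0.71). Of 19 SET and histone chaperone partners, 13 rose (14 adjusted over the list alone) and none fell, with a median of 0.39 (adjusted p = 2.51e-05, and adjusted p = 0.187 with an estimated correlation). PTMA, the abundant acidic nuclear protein prothymosin alpha, rose from 953 ± 13.4 to 1797 ± 21.1 FPKM (0.91), and the histone chaperones NASP (0.77), ASF1A (0.74) and CHAF1A (0.88) rose too. Of 19 Polycomb genes, 6 rose and 9 fell, with a median of -0.10 (adjusted p = 0.893); EZH2, the histone methyltransferase subunit, rose from 15.7 ± 1.03 to 26.9 ± 1.40 FPKM and CBX7, a chromatin reader, fell from 19.7 ± 1.14 to 9.59 ± 1.08 FPKM. Of 12 genes of the RNA interference machinery, through which an siRNA acts, 6 rose and 1 fell, with a median of 0.19 (adjusted p = 0.0768). DICER1 rose by 0.62 and EIF2C4, an Argonaute, fell by 0.86.

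Tumour-initiating features are named in the series title. Of 14 tested lung tumour-initiating cell markers, 7 rose and 4 fell, with a median of 0.19 (adjusted p = 0.116), so camera did not call the list higher than other genes, while fry, which does not compare it with other genes, called it higher (adjusted p = 1.63e-06). The aldehyde dehydrogenases ALDH1A1 (31.7 ± 2.31 to 98.1 ± 6.93 FPKM, 1.60) and ALDH3A1 (0.88) and the surface proteins CD24 (0.68) and ALCAM (0.62) were among those that rose. Of 5 tested pluripotency and stemness factors, 2 rose and 2 fell (adjusted p = 0.824): MYC (0.23) and KLF5 (0.48) rose, and KLF4 (-0.44) and SALL4 (-0.41) fell. Of 9 genes of the neural crest FOXD3 network, 3 rose and 4 fell, with a median of 0.16 (adjusted p = 0.717); ID3, an inhibitor of basic helix-loop-helix factors, rose by 1.34 and ETS1 fell from 8.48 ± 0.154 to 3.54 ± 0.288 FPKM. SALL4 and SNAI2, the latter at -0.37, were no longer called with quantile normalization. Of 25 Wnt pathway genes, 8 rose and 8 fell (adjusted p = 0.927), with the ligand WNT9A higher (1.01) and WNT10A lower (-1.87). Of 20 Notch pathway genes, 3 rose and 6 fell (adjusted p = 0.824), with NRARP higher (0.77) and DTX2 lower (-0.83). The medians of the pluripotency, Wnt and Notch lists were -0.10, -0.05 and -0.08 and turned to 0.02, 0.03 and 0.02 with quantile normalization.

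Matrix and mesenchymal genes were lower. Of 19 mesenchymal transition genes, 14 fell and 1 rose, with a median of -0.74, and -0.48 with no filter, which takes in the 27 listed (adjusted p = 0.000872, and adjusted p = 0.187 with an estimated correlation). FN1, fibronectin, fell from 749 ± 95.2 to 303 ± 12.6 FPKM (-1.30), and TAGLN, an actin-binding protein, from 8.29 ± 0.994 to 2.30 ± 0.295 FPKM (-1.49). Of 25 extracellular matrix and collagen genes, 18 fell (19 adjusted over the list alone) and none rose, with a median of -0.53 (adjusted p = 3.8e-05, and adjusted p = 0.187 with an estimated correlation). The collagen VI chains COL6A1 (-1.66) and COL6A2 (16.4 ± 2.32 to 1.38 ± 0.284 FPKM, -2.87) and the laminin chain LAMA3 (-1.39) fell. Of 24 TGF-beta response genes, 13 fell and 5 rose (6 adjusted over the list alone), with a median of -0.41 (adjusted p = 0.077), and SMAD3, a transducer of the pathway, fell from 38.3 ± 2.78 to 18.7 ± 0.453 FPKM. Of 26 Hippo-YAP target genes, 17 fell and 5 rose, with a median of -0.29 (adjusted p = 0.0657), among them the receptor kinase AXL (41.4 ± 1.78 to 14.4 ± 0.643 FPKM) and CYR61 (-1.40). With quantile normalization the TGF-beta and Hippo-YAP lists were called lower (adjusted p = 0.0312 and 0.00918). Of 21 MAPK feedback and EGFR ligand genes, 12 fell and 2 rose, with a median of -0.25 (adjusted p = 0.077), and the EGFR ligands HBEGF (-2.31) and AREG (-1.64) fell. Of 29 epithelial adhesion and junction genes, 13 fell and 8 rose, with a median of -0.11 (adjusted p = 0.838); CLDN1, a tight junction protein, fell from 33.8 ± 4.58 to 10.3 ± 1.36 FPKM and PKP3, a desmosomal protein, rose from 31.3 ± 2.11 to 52.6 ± 3.22 FPKM.

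The stress programmes went different ways. Of 33 genes of the ATF4 integrated stress response, 31 fell and 1 rose, with a median of -0.91 (adjusted p = 6.28e-10, and adjusted p = 0.187 with an estimated correlation). ASNS, which makes asparagine, fell from 147 ± 9.53 to 35.9 ± 3.07 FPKM and CHAC1, which degrades glutathione, from 21.2 ± 0.737 to 4.38 ± 0.242 FPKM (-2.04). Of 28 p53 target genes, 17 fell and 5 rose, with a median of -0.43 (adjusted p = 0.0431, and adjusted p = 0.187 with an estimated correlation), and this call was lost with no filter (adjusted p = 0.0629) and with array weights (0.0501). The cell cycle inhibitor CDKN1A fell from 35.1 ± 3.45 to 13.5 ± 0.678 FPKM (-1.31), and the stress cytokine GDF15 (-1.94) and the proapoptotic BBC3 (-1.69) fell. Of 24 apoptosis regulators, 13 fell and 4 rose, with a median of -0.25 (adjusted p = 0.074), with the proapoptotic PMAIP1 (-1.58) and the inhibitor of apoptosis BIRC3 (-1.73) both lower. Of 31 autophagy and lysosome genes, 18 fell and 2 rose, with a median of -0.30 (adjusted p = 0.0227, and adjusted p = 0.187 with an estimated correlation); GABARAPL1, of autophagosomes, fell from 93.2 ± 4.92 to 39.3 ± 0.818 FPKM and GLA, a lysosomal galactosidase, rose from 19.7 ± 0.795 to 52.6 ± 1.81 FPKM. Of 24 unfolded protein response genes, 14 rose and 5 fell, with a median of 0.28 (adjusted p = 0.00244, and adjusted p = 0.424 with an estimated correlation), among them the chaperones HSP90B1 (242 ± 26.2 to 518 ± 6.96 FPKM) and CALR (0.93). Of 34 NRF2 target genes, 21 rose and 6 fell, with a median of 0.28 (adjusted p = 8.14e-05, and adjusted p = 0.187 with an estimated correlation); UGDH, which makes UDP-glucuronate, rose from 62.1 ± 5.77 to 190 ± 1.43 FPKM, while AKR1B1, aldose reductase, fell from 1485 ± 67.6 to 619 ± 8.99 FPKM.

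In metabolism, 16 of 24 cholesterol biosynthesis genes fell and 3 rose, with a median of -0.44 (adjusted p = 0.0227, and adjusted p = 0.656 with an estimated correlation). The sterol oxidase MSMO1 fell from 78.2 ± 7.75 to 36.8 ± 1.79 FPKM and the sterol reductase TM7SF2 from 21.5 ± 2.43 to 9.03 ± 0.391 FPKM. Of 21 fatty acid synthesis and storage genes, 12 fell and 4 rose, with a median of -0.23 (adjusted p = 0.116), and SCD, the stearoyl-CoA desaturase, fell from 395 ± 31.8 to 151 ± 22.6 FPKM. With quantile normalization the list was called lower (adjusted p = 0.0216). Of 32 glycolysis and hypoxia genes, 14 rose and 10 fell (11 adjusted over the list alone), with a median of 0.19 (adjusted p = 0.203); the glycolytic enzymes ENO1 (1.01) and LDHA (1.01) rose, and the enolase ENO2 (-1.06) and the aldolase ALDOC (-2.13) fell. Of 56 nuclear-encoded genes of oxidative phosphorylation, 24 rose and 11 fell, with a median of 0.11, or 0.19 above the all-gene median, and 0.20 with median-of-ratios scaling (adjusted p = 0.0227, and adjusted p = 0.707 with an estimated correlation). COX7B, a cytochrome oxidase subunit, rose by 0.64 on the log2 scale and NDUFB9, of complex I, by 0.62. This call was lost with quantile normalization (adjusted p = 0.992), where the median was 0.03 with 18 genes higher and 19 lower. It was also lost with the stricter filter (adjusted p = 0.0891) and without siNC replicate 2 (0.113, median 0.075) or siNC replicate 3 (0.0621), and fry did not call the list (0.0983).

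Of 69 ribosomal protein genes, 58 fell and 4 rose (5 adjusted over the list alone), with a median of -0.26, or -0.18 relative to the all-gene median (adjusted p = 5.67e-07, and adjusted p = 0.393 with an estimated correlation). RPL13A fell from 1156 ± 37.2 to 467 ± 9.08 FPKM (-1.31) and RPS9 from 2017 ± 43.7 to 1287 ± 35.5 FPKM (-0.65). With quantile normalization 39 of these genes were called lower and 11 higher, with a median of -0.14. The median was -0.17 with median-of-ratios scaling and -0.15 after the trend on transcript length and GC content was removed, and the many pseudogenes of these genes can share reads. Removing that trend also centred the values over all genes, so -0.15 compares with -0.18 rather than with -0.26. Of 16 housekeeping reference genes, 10 rose and 3 fell, with a median of 0.31 (adjusted p = 0.0334, and adjusted p = 0.214 with an estimated correlation), and this call was lost with quantile normalization (adjusted p = 0.157), with the stricter filter (0.0786) and without siNC replicate 2 (0.066). TFRC, the transferrin receptor, rose from 58.7 ± 4.95 to 135 ± 4.79 FPKM, POLR2A, the large subunit of RNA polymerase II, rose from 30.9 ± 1.32 to 57.2 ± 0.647 FPKM, and B2M, the light chain of HLA class I, fell from 703 ± 51.2 to 347 ± 12.2 FPKM.

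**Figure D3:**
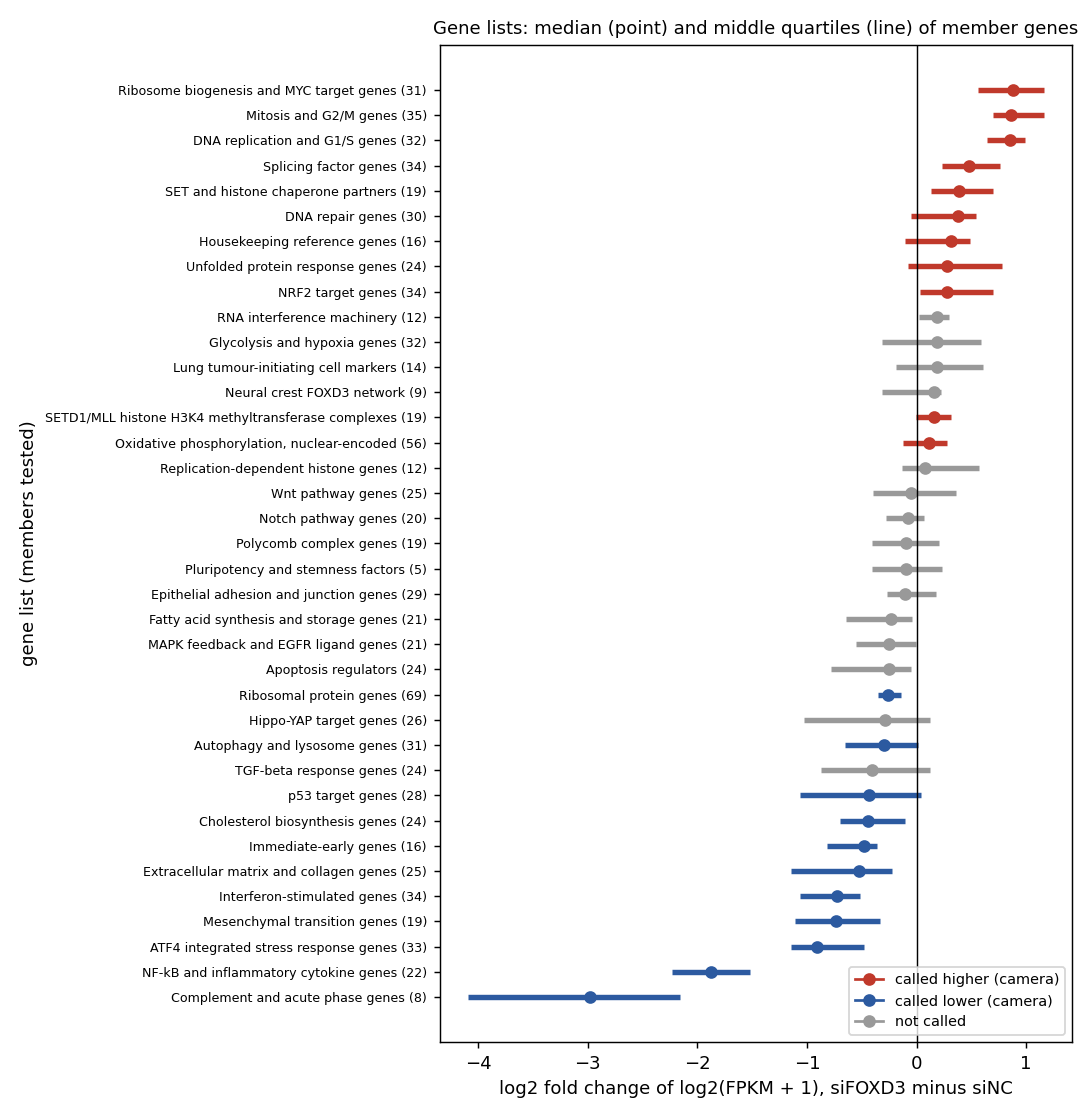
Log2 fold change, siFOXD3 minus siNC, of the members of the 37 pathway lists tested, with the median of each list (point) and its middle quartiles (line), coloured by camera's call. The medians run from -2.98 for complement and acute phase genes to 0.88 for ribosome biogenesis and MYC target genes. Quantile normalization turned the medians of the pluripotency, Wnt and Notch lists above 0.

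The median and the tests differed in sign for some lists that were not called. The pluripotency and Wnt lists had medians and means below 0 (means -0.05 and -0.14) and fry's direction was down (adjusted p = 0.998 and 0.0025) while camera's direction was up. The neural crest, glycolysis and histone lists had medians above 0 (means 0.04, 0.05 and 0.13) and camera's direction was up, while the direction of fry, which asks whether a list's genes move one way on balance, was down (adjusted p = 0.406, 0.912 and 0.943).

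Most markers of other cell types were below the filter on low values. Of 20 alveolar and airway epithelial markers, 6 were tested, of which 3 fell and 1 rose, with a median of -0.26 (adjusted p = 0.927); LAMP3, a lamellar body protein, fell from 2.93 ± 0.286 to 1.34 ± 0.135 FPKM and KRT5, a basal cell keratin, rose from 0.542 ± 0.139 to 2.54 ± 0.0122 FPKM. The highest of this list was the mucin MUC5B, at 9.43 ± 0.571 and 10.5 ± 0.760 FPKM (limma, Benjamini-Hochberg adjusted p = 0.153). The other lists of this kind had fewer than 5 tested members and are given as values. Among the retina and photoreceptor markers, listed because the extraction text of the labels speaks of retinas, ABCA4 rose from 1.62 ± 0.260 to 2.82 ± 0.153 FPKM and GNGT1 fell from 2.58 ± 1.08 to 0.962 ± 0.151 FPKM. The highest fibroblast marker was the collagen COL1A1, at 3.91 and 3.20 FPKM (limma, Benjamini-Hochberg adjusted p = 0.0691), with a log2 fold change of -0.22 that turned to 0.04 with quantile normalization. Of the endothelial markers, ESAM fell from 4.30 ± 0.251 to 2.09 ± 0.167 FPKM and CDH5 from 2.73 ± 0.355 to 1.82 ± 0.124 FPKM, the latter no longer called with quantile normalization. The highest hepatocyte marker was HNF4A, at 0.254 and 0.129 FPKM. Of the neural and neural crest-derived markers, the glycolytic enzyme ENO2 fell from 41.1 ± 2.03 to 19.2 ± 1.66 FPKM and the microtubule protein MAP2 from 10.8 ± 0.992 to 8.18 ± 0.392 FPKM, and the tubulin TUBB3 lay at 19.3 ± 3.40 and 22.8 ± 0.412 FPKM (adjusted p = 0.0595). None of the 15 mitochondrially encoded genes was listed, and of the small structured RNAs, SNORD17 averaged 22.3 ± 11.7 and 27.3 ± 13.5 FPKM and RPPH1 1.88 ± 0.964 and 2.51 ± 2.40 FPKM, neither called.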

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

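The alternatives were chosen before the data were examined, and none was added later. Over 62 results and 1099 alternative values, 1065 kept their direction and their side of the threshold (counts within 1.5 times), 20 kept the direction and lost the call, 12 counts moved by more than 1.5 times, and 2 reversed. The 2 reversals were RPS12 (0.039) and RPL41 (0.25) with quantile normalization, and the cause was not tested. The test against a fold of 1.2 called 4297 genes (1621 higher, 2676 lower), by its construction fewer. Counts of genes past a log2 change of 1 were 347 higher and 1246 lower with a pseudocount of 0.1, and 99 and 223 with a pseudocount of 5, which by construction stretches or shrinks changes of low genes. They were 423 lower with the stricter filter, which tests fewer genes, and 332 higher with quantile normalization, where the cause was not tested. Lists called with an estimated correlation were 2 higher and 1 lower, and fry, which does not compare a list with other genes, called 12 higher and 20 lower. Calls of fry that camera made under no setting were epithelial adhesion (fry adjusted p = 0.0238), Polycomb (0.00606), Notch (0.00184) and Wnt genes (0.0025) lower and tumour-initiating markers (1.63e-06) higher. Beyond camera's reported calls, fry also called TGF-beta (fry adjusted p = 1.05e-05), Hippo-YAP (1.56e-05), apoptosis (1.56e-05), MAPK (0.000104) and fatty acid genes (0.00474) lower. It called RNA interference genes (0.0269) higher and lost oxidative phosphorylation (0.0983).

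The number of genes called was 7278 to 7974 when a library was left out, and 6682 at an adjusted p of 0.01 (limma, Benjamini-Hochberg). Of 8278 calls, 6972 were shared with quantile normalization, 6 genes being called in the opposite direction. Without 1 library, 9 to 12 lists were called higher and 12 to 15 lower. With camera, lists not called as reported were called lower in at least 1 alternative for apoptosis, fatty acid, Hippo-YAP, MAPK and TGF-beta genes, and higher for glycolysis (without siNC replicate 1) and RNA interference genes (no filter). WDR5 lay between 0.69 and 0.76 and SET between 0.53 and 0.58 with a library left out, and both stayed called under each alternative computed for single genes, and in the test against a fold of 1.2 (adjusted p = 0.000104 and 0.000295). The FOXD3 percentage ran from 0 to 19.5 with a library left out, since single fragments decide it at this depth. It was given as a percentage after the data were seen, because a difference in FPKM changes with the unit when values are rescaled to TPM.

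Replicate numbers are shared by the groups. The correlations of deviations of same-numbered libraries were 0.061, 0.163 and 0.115, so the numbers were not taken as pairs, although every sample correlated best with its own number, a hint from the data and not from the design. With the replicate block, limma called 8172 genes, 3354 higher and 4818 lower.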

Other observations

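The groups of genes in this part, FOXD1 and WDR5B, and the tests on leukocyte markers, on sequencing depth and on snoRNA values were chosen after the results were seen, as were the margin used to read the seed test, the comparison of NF-kB genes with and without the seed word and the test on the neighbours of growth genes. Antigen presentation genes were lower in siFOXD3: of 20 tested, 16 fell and 3 rose, with a median log2 fold change of -0.96 (camera, adjusted p = 0.000385 over 8 groups, and adjusted p = 0.212 with an estimated correlation). HLA-B, a class I heavy chain, fell from 62.2 ± 8.59 to 6.77 ± 0.529 FPKM (mean ± SD, n = 3). The peptide transporter subunits went apart, TAP1 falling from 17.4 ± 1.35 to 9.09 ± 0.417 FPKM and TAP2 rising from 32.1 ± 1.62 to 39.3 ± 1.32 FPKM. HLA genes are polymorphic and share reads, so their levels are uncertain. Of 20 genes of Toll-like and IL-1 receptor signalling, 12 fell and 3 rose, with a median of -0.70, or -0.43 with quantile normalization (adjusted p = 0.034, and adjusted p = 0.235 with an estimated correlation), and TNIP1, an inhibitor of NF-kB signalling, fell from 184 ± 13.8 to 44.9 ± 2.58 FPKM. The 3 that rose were IRAK1 (0.823), IL1RN (0.821) and MYD88 (0.215), while the falls include cytokine genes such as IL32 (-3.06) and TNFSF15 (-2.09). A group picked from these same data cannot show that receptor signalling as such was lower. S100A9, the partner of S100A8, fell from 1885 ± 250 to 360 ± 28.5 FPKM, but the S100 and cornified envelope group was not called (6 of 24 rose and 12 fell, adjusted p = 0.215).

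Chaperonin, HSP90 and nuclear transport genes were higher. Every group in this part, antigen presentation included, was picked after the results of the same libraries were seen. The adjusted p-values of these groups are therefore descriptive and give no independent support. Of 16 chaperonin and HSP90 genes, 13 rose and none fell, with a median of 0.79 (camera, adjusted p = 5.1e-08, and adjusted p = 0.117 with an estimated correlation), and HSP90AA1, a cytosolic chaperone, rose from a mean of 807 to 1974 FPKM (log2 fold change 1.29 ± 0.03, SE). Of 45 nuclear transport genes, 32 rose and 4 fell, with a median of 0.35 (adjusted p = 3.94e-08, and adjusted p = 0.117 with an estimated correlation), and KPNA2, an importin, rose from 81.3 ± 7.40 to 175 ± 1.16 FPKM. Of 9 cancer-testis genes, 5 rose and 1 fell, with a median of 0.77 (adjusted p = 0.0146, and adjusted p = 0.212 with an estimated correlation). Their near-identical copies share reads, and the group holds SPANXA2 and SPANXB2, already named among the largest rises. Keratin genes (9 of 18 rose, 7 fell, adjusted p = 0.158) and metallothionein genes (1 of 5 rose, 2 fell, adjusted p = 0.825) were not called. Of 132 families of genes with a shared symbol prefix, camera called 16 higher and 5 lower, and with an estimated correlation the lowest adjusted p was 0.527. FOXD1, a relative of FOXD3, was at 1.96, 1.63 and 1.33 FPKM in siNC and 0.509, 0.277 and 0.511 FPKM in siFOXD3, and WDR5B, a relative of WDR5, at 3.46 to 4.71 FPKM in siNC and 2.11 to 2.78 FPKM in siFOXD3.

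The count of 8278 called genes was compared with other splits of the libraries. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 8278 genes, the highest of the other splits called 1, and 1 split, the real one, reached the real count. Each of the other splits mixes siNC with siFOXD3 libraries, so the group difference raises the spread inside its sides and lowers its count. That count of 1 is therefore not an estimate of false calls.

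For the fall of inflammatory genes, a pattern to follow up, scaling is argued against, since the NF-kB list's median nearest 0 over 3 rescalings was -1.82. Leukocytes among the siNC cells are argued against as well: 4 of 17 leukocyte markers reached 1 FPKM in any siNC library and PTPRC averaged 0.227 FPKM, while LCP1 was at 95.2 FPKM. For a seed-matched off-target effect of the siRNA, words of 7 bases found in the FOXD3 transcript or its reverse complement were scanned. The lowest t of such a word was -4.08, short of a Bonferroni bound of -4.52 and close to the lowest of other words (-4.12). Of the 21 NF-kB genes scanned, 61.9% carried that word against 28.8% of other genes. However, its 3382 carriers differed by a mean of -0.043, and the NF-kB genes with and without it had medians of -1.84 and -1.88. These values argue against that word acting directly on each of these genes, while another word, or an off-target on a gene upstream of them, stays open. Loss of FOXD3 itself (estimated fragment ratio 0.105) cannot be told apart from anything else that differed between the groups, because a single siRNA group stands against a single control group, and it may or may not account for the pattern.

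For the rise of growth genes, another pattern, transcript length and GC content are argued against, since after their trend was removed (3.0% of the variance) the medians of the mitosis and ribosome biogenesis lists were 0.89 and 1.00. Removing that trend also centred the values over all genes. Relative depths differed by at most 1.09 times and estimated fragments by 1.17 times, short of the 1.5 times set as the bound for a depth effect. For a different subline of A549 with other chromosome copy numbers, the outcome predicted beforehand was met by only 1 of 110 windows of 100 neighbouring genes. Its median lay 0.301 above the genome median, just past the bound of 0.3, against 0 windows in 100 shuffled orders. That window, from WASH7P to DFFA on chromosome 1, held no mitosis or ribosome biogenesis genes, and so small a margin cannot decide the question. Other copy numbers of the 66 mitosis and ribosome biogenesis genes themselves are argued against, since the 10 nearest tested neighbours of each of the 66 had a median of -0.02 relative to all genes (95% bootstrap interval -0.07 to 0.05), short of the 0.4 set as the bound. The DNA replication list was not part of that test. A subline whose copy numbers act on these genes through regulators elsewhere, loss of FOXD3, and a change of growth state such as cell density stay open as untested hypotheses.

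Some snoRNA genes stood above 100 FPKM in 1 library and were absent from others. Between 100 and 1500 FPKM, 7.0% of snoRNA values (8 of 115) were shared exactly with another snoRNA of the same library, against 0.4% of values of other genes (18 of 4526; two-sided Fisher's exact test, p = 1.2e-07). The shared values came from siNC replicate 3 (2 of 18), siFOXD3 replicate 2 (2 of 24) and siFOXD3 replicate 3 (4 of 23) and from none of the other libraries; without siFOXD3 replicate 3 the share was 4.3% (4 of 92, two-sided Fisher's exact test, p = 0.0016). The test counts values of the same genes in several libraries as if independent, so its p is too small. The shares are consistent with single fragments on very short genes, where the length division yields large FPKM values from 1 fragment, for the libraries that hold them. No biological explanation of this pattern was tested.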
